A study of Mus musculus with 2 samples.

How the data were processed

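Pancreata of 1 control and 1 knockout-titled C57BL/6 mouse embryo of embryonic day 13.5 were dissociated with trypsin, and live cells (7-AAD negative) were sorted and loaded for a target of 5000 cells with 10x Chromium 3' version 2 chemistry, per the labels' protocols. Groups were taken from the sample titles. The deposited matrices hold UMI counts per gene and barcode, made with Cell Ranger on the mouse genome GRCm38, per the submitters' processing notes, which also name Seurat 2 and 3 without a role. The version of Cell Ranger, the aligner and the annotation release are not given in the sources used here. The matrices hold 3900 and 3044 barcodes, and a matrix of all droplets was not used here. A further deposited table gives, per the file headers, an average log fold for each gene and cluster, read here as the natural log that Seurat 2 and 3 write, and its p-values over cells were not used.

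From the counts, cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. This removed 29 control and 32 knockout-labelled barcodes, of which 27 and 28 had most of their UMIs on haemoglobin genes. A doublet score from simulated doublets (2 per cell) was computed per library, and the highest-scoring 0.8% per 1000 barcodes were removed, 122 and 74 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 (seed 0), which gave 25 clusters. The epithelium was clustered again at resolution 1.0 into 11 clusters. Clusters were named from marker genes fixed before the data were examined, with at least 3 detected markers. A name also needed a marker of its class among the cluster's 10 leading genes, and no more markers of another class there. Mural markers ran through the mesenchyme, so mural and mesenchymal clusters were merged into mesenchyme-like after seeing the data, as were glial and neuronal clusters into neural-like. A cluster of 11 control and 41 knockout-labelled cells scored best for mesenchyme, with 7 markers detected. It had 0 markers of that class and 1 of another among its 10 leading genes, so it met no name and stayed out of the classes.

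UMI counts were summed per library and class and given as CPM, with all genes in the total. Ratios are log2 of (CPM + 5) of the knockout-labelled library over the control library. CPM intervals are exact Poisson, shares have exact Clopper-Pearson intervals, ratios of shares have log-normal intervals, and list medians have intervals from 1000 Poisson resamples, all at 95% and for counting error alone. For a count of 0 the limit given is 3 counts over the total, which is below the upper bound of the exact interval. With 1 library per group no test was run. The 17 gene lists were fixed before the data were examined, members needed at least 20 UMIs over both libraries, and each median was placed among 10000 random lists matched on expression in 20 bins. The names Amy2b, Spink3 and Rian were not matched in the files. The classes compared outside the epithelium had at least 50 cells in each library.

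The genes named follow a rule fixed before the data were examined. Among genes with at least 50 CPM in a library and at least 20 UMIs over both, it takes the 12 highest and 12 lowest ratios in the epithelium, the 6 highest and 6 lowest by the epithelial minus the mesenchymal ratio, the 6 highest and 6 lowest in mesenchyme, and the 4 highest and 4 lowest in each epithelial class and in mesothelium. Ribosomal protein, mitochondrial, haemoglobin and sex-linked marker genes and gene models without a name were left out of the ranking. Dpy30, list members and the genes left out may be named as examples.

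The steps were tested on simulated counts of the epithelial comparison, with 200 of 2633 genes made 1.5-fold, 2-fold or 4-fold different. The simulated counts were Poisson, as the intervals assume, without variation between cells or embryos, so they check the arithmetic alone. The fold interval held the true fold for 89.6% of 67 genes at 1.5-fold, 97.0% of 67 at 2-fold, 97.0% of 66 at 4-fold and 96.2% of 2433 unchanged genes. The interval of a list median held the true median in 99.6% of 500 lists of 20 unchanged genes.

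Alternatives fixed before the data were examined were no cell filter, a stricter filter (1500 genes, 5% mitochondrial), no doublet removal or 2 times the rate, resolutions 0.5 and 2.0, centring within library, clustering without cell cycle genes, seed 1, a gate on epithelial UMIs, median-of-ratios and TMM scaling, mean CPM over cells, CPM without haemoglobin, mitochondrial and ribosomal genes, thinning to 3000 or 5000 UMIs, pseudocounts of 1 and 20, list minimums of 1 and 100 UMIs, the mean of the class log2 ratios weighted by share of cells, the epithelial minus mesenchymal ratio and subtraction of background RNA. Clustering without marker and list genes and leaving out the cells of epithelial cluster 5 (for list medians, gene ratios and shares) were chosen after seeing the data. So was combining the CPM of the epithelial classes with the same weights in both libraries, the mean of their shares of epithelial UMIs, with intervals from 1000 Poisson resamples. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used, with edgeR 4.0.16 in R 4.3.3 for TMM factors. Gene positions come from GENCODE M21 on GRCm38, in which 27645 of the 27998 gene IDs of the files were found, and 65 symbols stand for more than 1 ID.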

Results

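Dissociated cells of 2 mouse pancreata at embryonic day 13.5 were profiled by droplet single-cell RNA sequencing, in which each transcript molecule carries a unique molecular identifier (UMI). One library came from a control embryo and the other from an embryo titled knockout, in a series about Dpy30, a core subunit of the Trithorax group (COMPASS) complexes that methylate histone H3. The control library held 3900 cell barcodes with 32702089 UMIs, a median of 6825.5 UMIs and 2240 genes per barcode. The knockout-labelled library held 3044 barcodes with 28033433 UMIs, a median of 8049 UMIs and 2455.5 genes. After filters, 3749 and 2938 cells were analysed. Each group is 1 library of 1 embryo, so no difference below has a replicate check and no test between conditions was possible. Intervals are 95% exact Poisson (CPM), exact binomial (shares) or resampled (list medians) and cover counting error alone. Cell classes are named after marker genes and written as "-like". Levels are CPM, the UMIs of a gene scaled to a common library total, and values joined by "against" give the control library first.

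Dpy30, the gene named by the series, was not lower in the epithelium of the library labelled knockout. In epithelium-like cells it stood at 226 CPM (95% interval 217 to 236) in the control library and 266 (254 to 279) in the knockout-labelled library, a log2 ratio of 0.23. In mesenchyme-like cells Dpy30 stood at 98.2 against 114 CPM (log2 ratio 0.20), in tip-like cells at 250.2 against 268 CPM and in trunk-like cells at 209.6 against 260.3 CPM. It was higher in the knockout-labelled library in endocrine-like cells (281 against 476 CPM) and lower in mesothelium-like cells (175 against 141 CPM). Dpy30 (ENSMUSG00000024067) lies on the minus strand of chromosome 17 from 74299474 to 74323944 in GRCm38. The deleted part of the gene is not given in the sources used here, and a 3' tag outside it checks nothing, so the knockout is known from the label alone. Among the other members of the COMPASS list, Ash2l stood at 78.5 against 74.4 CPM and Kmt2a at 35.2 against 42.7 CPM in the epithelium, and 10 of its 18 measured members were higher, with a median log2 ratio of 0.12 (interval -0.019 to 0.17).

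The embryos were of opposite sex. Xist, the RNA of the inactive X chromosome, had 0 UMIs in the control library and 9755 in the knockout-labelled library in epithelium-like cells, the Y-linked Ddx3y had 440 UMIs in the control library and 0 in the knockout-labelled library, and Eif2s3y had 346 UMIs in the control library and 0 in the knockout-labelled library.

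The first comparison asked how the cells were divided among classes. Epithelium-like cells made up 749 of 3742 control cells (20.02%, interval 18.7 to 21.3) and 468 of 2929 cells of the knockout-labelled library (15.98%, 14.7 to 17.4). Within this epithelium, tip-like cells, which carry acinar genes, made up a larger share in the knockout-labelled library, and endocrine progenitor-like and endocrine-like cells made up smaller shares. Tip-like cells were 188 of 749 control cells (25.1%, interval 22.03 to 28.4) and 191 of 468 cells of the knockout-labelled library (40.8%, 36.3 to 45.4), a ratio of 1.63 (interval 1.38 to 1.92). Endocrine progenitor-like cells were 123 of 749 control cells (16.4%, interval 13.8 to 19.3) and 48 of 468 cells of the knockout-labelled library (10.3%, 7.66 to 13.4), a ratio of 0.625 (interval 0.457 to 0.854). Endocrine-like cells were 91 of 749 control cells (12.1%, interval 9.90 to 14.7) and 24 of 468 cells of the knockout-labelled library (5.13%, 3.31 to 7.53), a ratio of 0.422 (interval 0.273 to 0.652). Trunk-like cells, the bipotent and ductal part of the epithelium, were 347 of 749 control cells (46.3%, interval 42.7 to 49.97) and 205 of 468 cells of the knockout-labelled library (43.8%, 39.3 to 48.4), whose intervals overlap. A single epithelial cluster, number 5, held 16 of the 188 tip-like control cells and 99 of the 191 of the knockout-labelled library, so it may be that library and not a cell type. Without the cells of cluster 5, all of them tip-like, an alternative chosen after seeing the data, the ratios were 1.06 (0.853 to 1.32) for tip-like, 1.17 (1.04 to 1.32) for trunk-like, 0.775 (0.569 to 1.06) for endocrine progenitor-like and 0.524 (0.340 to 0.807) for endocrine-like cells, so that the intervals of the tip-like and endocrine progenitor-like ratios include 1. Cluster 5 was picked for its excess in the knockout-labelled library. Leaving it out therefore lowers the tip-like ratio and raises those of the other classes by a common factor, by construction. The ratios without it describe shares of the remaining epithelial cells and do not test the other classes. When the marker genes and all listed genes were left out of the clustering, likewise chosen after seeing the data, the ratios were 1.64 for tip-like, 0.585 for endocrine progenitor-like and 0.405 for endocrine-like cells.

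**Figure D1:**
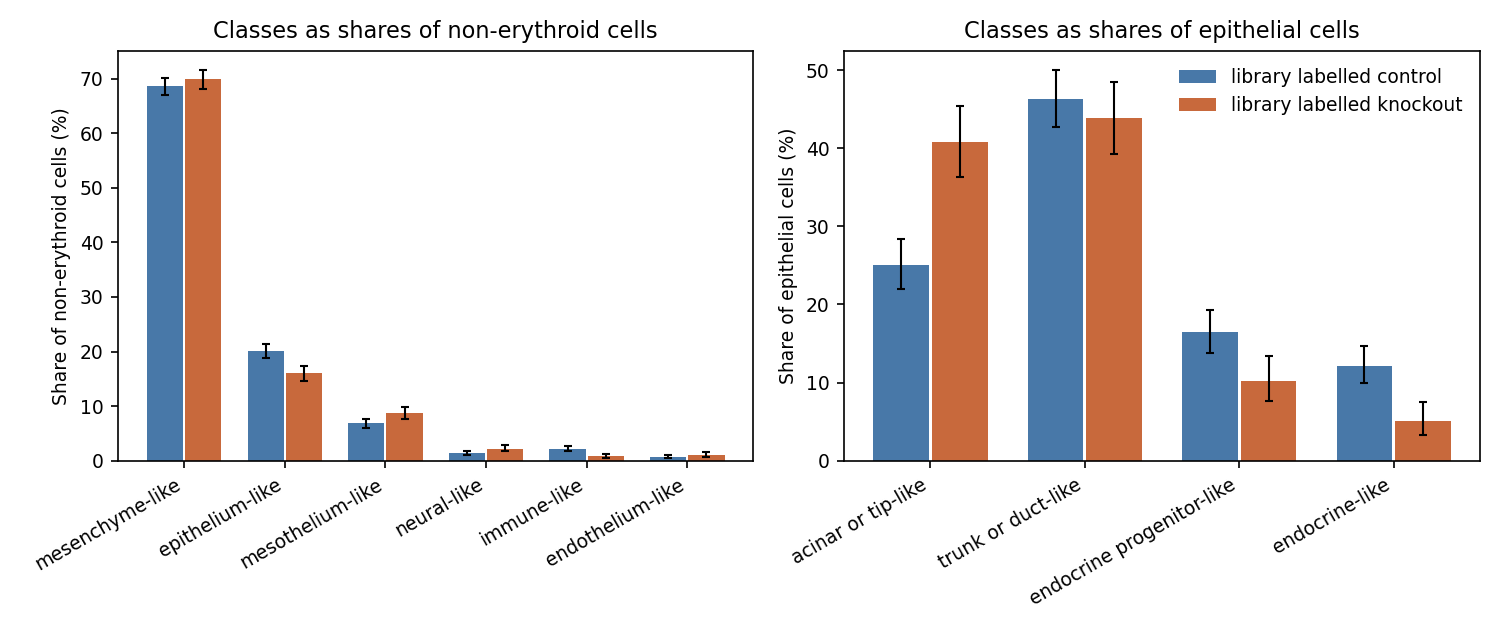
Share of cells (%) in each class for the control library and the library labelled knockout, on the left among non-erythroid cells and on the right among epithelial cells; bars are the shares of 1 library each and error bars the exact binomial 95% intervals of counting error. Tip-like cells took 25.1% of the control and 40.8% of the knockout-labelled epithelium, and endocrine-like cells 12.1% and 5.13%.

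Outside the epithelium, mesenchyme-like cells were 2566 of 3742 control cells (68.6%, interval 67.1 to 70.1) and 2047 of 2929 cells of the knockout-labelled library (69.9%, 68.2 to 71.5). Mesothelium-like cells were 256 of 3742 control cells (6.84%, interval 6.05 to 7.70) and 254 of 2929 cells of the knockout-labelled library (8.67%, 7.68 to 9.75). Immune-like cells were fewer in the knockout-labelled library, with 83 of 3742 control cells (2.22%, interval 1.77 to 2.74) and 23 of 2929 cells of the knockout-labelled library (0.785%, 0.498 to 1.18). Neural-like cells were 49 of 3742 control cells (1.31%, interval 0.970 to 1.73) and 64 of 2929 cells of the knockout-labelled library (2.19%, 1.69 to 2.78), and endothelium-like cells were 28 of 3742 control cells (0.748%, interval 0.498 to 1.08) and 32 of 2929 cells of the knockout-labelled library (1.09%, 0.748 to 1.54). Live cells were sorted and a fixed number loaded, so these are shares and not cell numbers per pancreas.

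Cells with a UMI of single genes were also counted over the whole epithelium, without the epithelial classes. Neurog3 encodes the transcription factor that starts endocrine differentiation, and after thinning each cell to 3000 UMIs it was seen in 191 of 743 control cells (25.7%, interval 22.6 to 29.01) and 81 of 466 cells of the knockout-labelled library (17.4%, 14.1 to 21.1). Without cluster 5 the ratio of the thinned Neurog3 shares was 0.838 (0.667 to 1.05), an interval that includes 1. This setting left 189 of 727 control and 80 of 367 knockout-labelled cells. It changed mainly the denominators and does not test the Neurog3 difference itself. Without thinning the cells with Neurog3 were 268 of 749 control cells (35.8%, interval 32.3 to 39.3) and 116 of 468 cells of the knockout-labelled library (24.8%, 20.9 to 28.96). In mesenchyme-like cells, which should lack it, the thinned Neurog3 shares were 0.828% and 0.0500%, with median depths before thinning of 6020.5 and 7273 UMIs against 12171 and 14333.5 in the epithelium. Chga, a granule protein of endocrine cells, was seen in 103 of 743 control cells (13.9%, interval 11.5 to 16.6) and 27 of 466 cells of the knockout-labelled library (5.79%, 3.85 to 8.32). Ptf1a, a transcription factor of multipotent tips and acinar cells, was seen in 29 of 743 control cells (3.90%, interval 2.63 to 5.56) and 56 of 466 cells of the knockout-labelled library (12.02%, 9.21 to 15.3). Pdx1 was seen in 212 of 743 control cells (28.5%, interval 25.3 to 31.9) and 139 of 466 cells of the knockout-labelled library (29.8%, 25.7 to 34.2) and Nkx6-1 in 176 of 743 control cells (23.7%, interval 20.7 to 26.9) and 109 of 466 cells of the knockout-labelled library (23.4%, 19.6 to 27.5), with overlapping intervals. Sox9 was seen in 44.7% (41.1 to 48.3) and 52.8% (48.1 to 57.4), Cpa1 in 35.4% (31.96 to 38.96) and 39.9% (35.4 to 44.5), Spp1 in 70.7% (67.2 to 73.9) and 62.4% (57.9 to 66.9) and Gcg in 3.23% (2.08 to 4.77) and 1.29% (0.474 to 2.78) of the thinned epithelial cells of the control and the knockout-labelled library. The thinned shares in mesenchyme-like cells of both libraries, as a background, were 7.53% and 7.15% for Cpa1, 5.36% and 2.55% for Spp1, 1.58% and 1.80% for Sox9, 0.631% and 0 of 1999 cells (limit 0.150%) for Gcg, 0.434% and 0.100% for Chga, 0 of 2536 cells (limit 0.118%) and 0.100% for Ptf1a, 0.0789% and 0.250% for Pdx1, 0.0789% and 0.100% for Nkx6-1 and 0.0394% and 0 of 1999 cells (limit 0.150%) for Ins1. Ins1 was seen in 9 of 743 and 0 of 466, for which the limit, taken as 3 counts of the cells, is 0.644%. Thinning left out 6 control and 2 knockout-labelled epithelial cells.

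Across the epithelium as a whole, genes of hormone-producing cells were lower in the library labelled knockout and Ptf1a, Reg1 and Vtn were higher. Ptf1a (chromosome 2, 19445663 to 19447501) stood at 21.4 CPM (95% interval 18.6 to 24.4) in the control library and 63.01 (57.2 to 69.2) in the knockout-labelled library. Reg1 stood at 37.3 against 98.6 CPM, Vtn at 138 against 315 CPM, and the serpins Serpina1b and Serpina1a at 177 against 348 CPM and 35.3 against 70.97 CPM. Tcea3, Matn4, the glucose transporter Slc2a2, Prss23 and Chst2 were also among the 12 genes highest by the naming rule, with log2 ratios of 1.03, 0.91, 0.79, 0.78 and 0.77. Scand1 and Eif3f completed the 12, but were higher to a similar degree in mesenchyme (1.09 and 1.13 for Scand1, 0.92 and 0.91 for Eif3f), so that Scand1 had the opposite sign, -0.048, and Eif3f 0.0094, with the mesenchymal ratio subtracted. Without cluster 5 the log2 ratios of Ptf1a, Reg1 and Vtn were 0.80, 0.72 and 0.54, against 1.37, 1.29 and 1.16 with it. With the CPM of the classes combined at equal class shares of UMIs in both libraries, likewise chosen after seeing the data, they were 1.01 (0.81 to 1.21), 0.99 (0.83 to 1.16) and 0.78 (0.69 to 0.88). Without cluster 5 Tcea3 stood at 0.69, Serpina1b at 0.65, Serpina1a at 0.74, Matn4 at 0.35, Slc2a2 at 0.81, Prss23 at 0.45 and Chst2 at 0.38. At equal class shares these genes stood at 0.83, 0.81, 0.83, 0.63, 0.83, 0.51 and 0.44. Sdpr was named by the difference from mesenchyme, at 44.5 against 72.4 CPM (log2 ratio 0.64). Without cluster 5 its log2 ratio was 0.15 (-0.060 to 0.34), which includes 0, and at equal class shares 0.37 (0.20 to 0.54). Cluster 5 holds mainly knockout-labelled cells, so the ratios without it describe the remaining cells and test no difference.

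At the other end, the hormone genes Iapp, Ghrl and Gcg had the lowest ratios in the epithelium. Iapp (chromosome 6, 142298423 to 142303961) stood at 109 CPM (95% interval 103 to 116) in the control library and 1.74 (0.898 to 3.04) in the knockout-labelled library. Gcg, which encodes glucagon (chromosome 2, 62474530 to 62483650), stood at 365 CPM (95% interval 353 to 377) in the control library and 51.1 (45.9 to 56.8) in the knockout-labelled library. Ghrl stood at 96.4 against 7.82 CPM, and in endocrine-like cells it was seen in 4 of 91 control and 1 of 24 knockout-labelled cells, so its ratio rests on few cells. The log2 ratio of Gcg was -2.72, and -1.49 after thinning, -1.61 as the mean over cells and -3.36 with the stricter cell filter. Pcsk2, Cck, Chgb, Chga, Pyy, Slc38a5, Pax6 and Isl1 followed with log2 ratios of -1.83, -1.55, -1.52, -1.52, -1.42, -1.35, -1.33 and -1.27. With the classes combined at equal shares of UMIs, the log2 ratios were -3.39 (-3.68 to -3.11) for Iapp, -1.91 (-2.22 to -1.62) for Ghrl, -1.30 (-1.46 to -1.15) for Gcg, -0.58 (-0.83 to -0.33) for Pcsk2, -0.72 (-0.85 to -0.60) for Cck, -0.18 (-0.25 to -0.13) for Chgb and -0.27 (-0.45 to -0.075) for Chga. For Pyy (-0.016 (-0.14 to 0.10)), Slc38a5 (0.0049 (-0.089 to 0.096)), Pax6 (-0.15 (-0.37 to 0.083)) and Isl1 (-0.049 (-0.25 to 0.13)) the intervals then included 0. All these intervals treat UMIs as independent, though many can come from the same cell. In endocrine-like cells Gcg was seen in 24 of 91 control and 6 of 24 knockout-labelled cells. An interval that excludes 0 is therefore no measure of the spread between cells. A mean of the log2 ratios of the classes weighted by their share of cells draws genes of 1 class toward 0 by construction, to -0.46 for Iapp and 0.36 for Ptf1a, and is not read further. The metallothionein Mt1 was the 12th, at 539.8 against 238 CPM (log2 ratio -1.16), and was also lower in mesenchyme (-0.86) and mesothelium (-0.72). Neurog3 (chromosome 10, 62133090 to 62134763) stood at 455 CPM (95% interval 442 to 468) in the control library and 247 (236 to 259) in the knockout-labelled library. At equal class shares of UMIs its log2 ratio was -0.27 (-0.35 to -0.20).

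**Figure D2:**
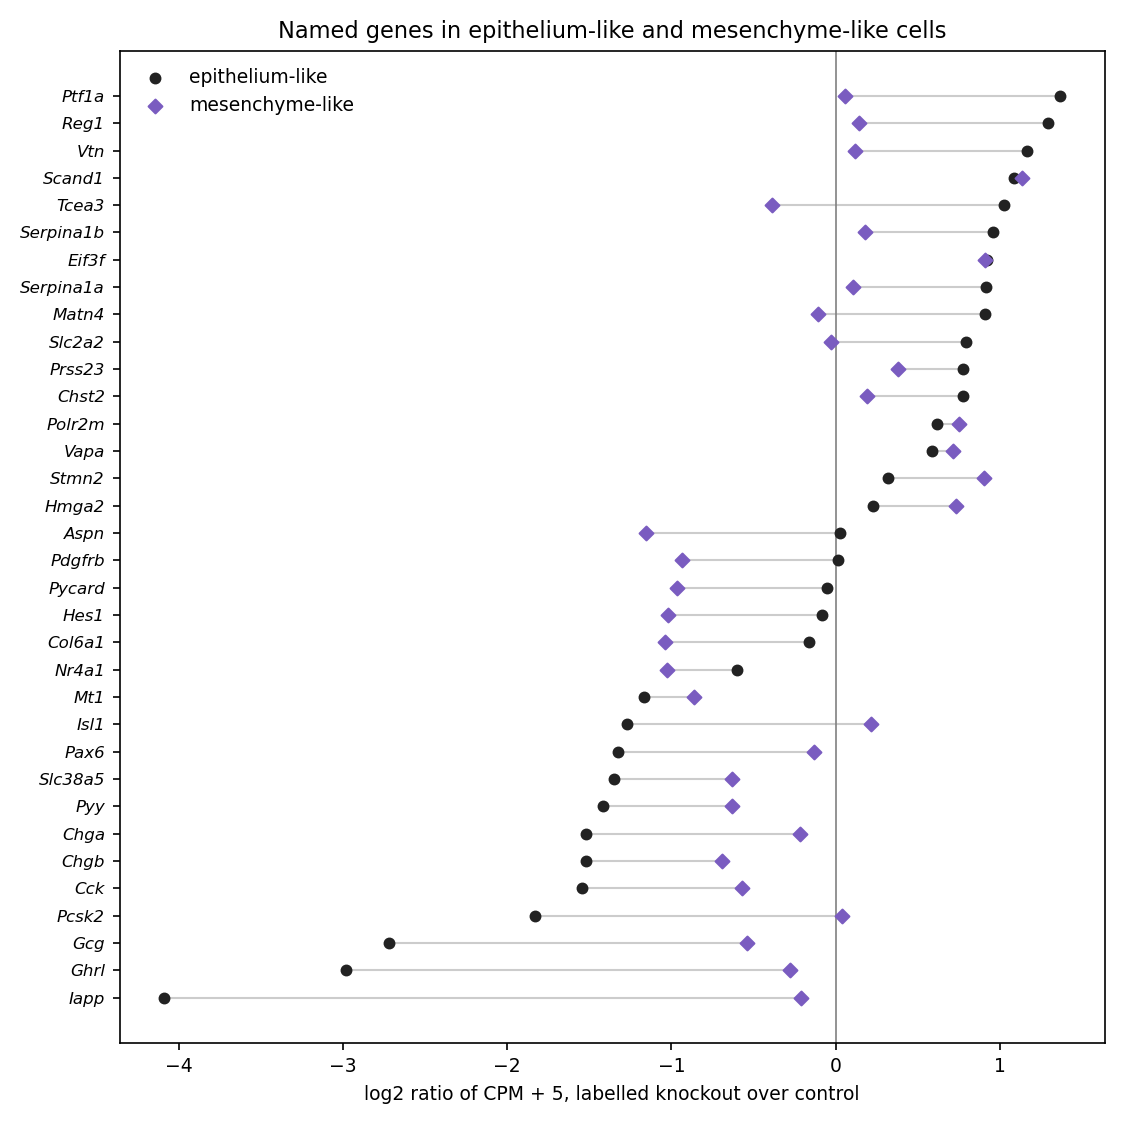
Log2 ratio of CPM + 5 (knockout-labelled library over control library) for each gene named in epithelium or mesenchyme, with circles for epithelium-like and diamonds for mesenchyme-like cells. Iapp, Ghrl and Gcg are lowest in the epithelium, at -4.09, -2.98 and -2.72, while Scand1 and Eif3f lie close together in both.

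Of the fixed gene lists, the endocrine hormone and islet genes had the lowest median in the epithelium, -1.17 (interval -1.31 to -1.06), and 28 of 28 measured members were lower. The endocrine progenitor genes had a median of -0.58 (interval -0.66 to -0.45), and 21 of 23 measured members were lower. Both medians lay below all 10000 random lists matched on expression. With the classes combined at equal shares of UMIs, an alternative chosen after seeing the data, the median of the hormone list was -0.13 (-0.22 to -0.061), with 20 of 28 members lower. That of the progenitor list was -0.072 (-0.15 to -0.0039), with 17 of 23 lower. In mesenchyme-like cells, as a background, the hormone list had a median of -0.28, and Gcg stood at 2.35 against 0.0644 CPM. The G2/M genes, which cells express around mitosis, had a median of -0.47 (interval -0.55 to -0.47), and 50 of 52 measured members were lower, among them Ube2c (387 against 189.9 CPM) and Ccnb1 (134.5 against 66.05 CPM). Pancreas progenitor transcription factors had a median of 0.15 (interval 0.070 to 0.21), and 16 of its 18 measured members were higher. Sox9 stood at 297 against 319 CPM, Pdx1 at 125 against 127 CPM and Nkx6-1 at 87.6 against 79.4 CPM.

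The acinar list had a median of -0.063 (interval -0.19 to 0.066) in the epithelium, which covers 0, and the duct and trunk list one of -0.17 (interval -0.26 to -0.094), with Spp1 at 2205 against 1393 CPM and Krt19 at 64.3 against 39.3 CPM. Of the 20 measured duct and trunk members 13 were lower and 7 higher. The highest was Vtn (log2 ratio 1.16), which in these data is a leading gene of the tip-like clusters and not of the trunk-like ones. Without cluster 5, an alternative chosen after seeing the data, the acinar median was -0.32, the duct and trunk median -0.032 and the S phase median 0.094. These 3 medians describe the remaining cells alone. The acinar median was -0.21 at equal class shares of UMIs, but 0.16 after thinning and 0.16 for members with at least 100 UMIs, so it has no direction here. Dissociation stress genes had a median of -0.29 (interval -0.32 to -0.23) and mitochondrially encoded genes one of 0.24 (interval 0.21 to 0.27), and both had the same sign in mesenchyme (-0.22 and 0.32), while in mesothelium the medians were 0.12 (interval -0.014 to 0.18) and 0.28. The haemoglobin gene Hbb-bs was higher in the knockout-labelled library in epithelium and mesenchyme, at 81.5 against 187 CPM and 82.1 against 207 CPM. The remaining lists had epithelial medians of -0.070 (S phase), 0.0093 (p53 targets), 0.073 (Notch pathway), -0.11 (Wnt and FGF feedback), 0.055 (imprinted), 0.042 (glycolysis and hypoxia), 0.035 (Hox and Polycomb targets, 3 measured) and -0.21 (other endoderm, 3 measured). With the mesenchymal ratio subtracted, the mitochondrially encoded median was -0.066 and the glycolysis and hypoxia median -0.055. In simulated data a shift of -0.027 in unchanged genes was enough for 41.8% of unchanged lists to have intervals that exclude 0, so medians this close to 0 carry no direction.

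**Figure D3:**
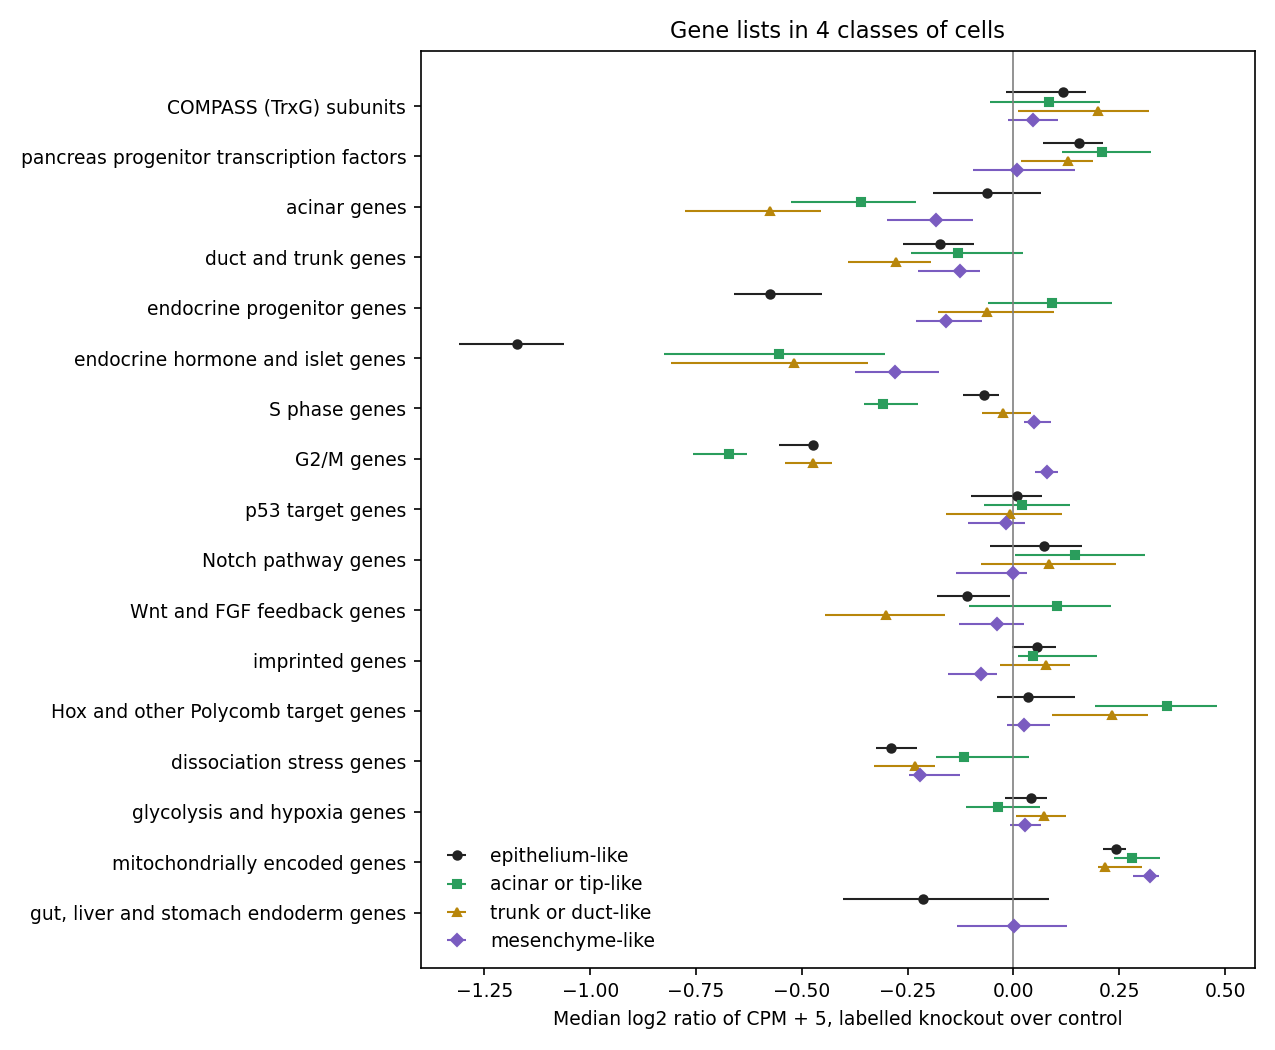
Median log2 ratio of CPM + 5 (knockout-labelled library over control library) of each fixed gene list in epithelium-like, tip-like, trunk-like and mesenchyme-like cells, with resampled 95% intervals of counting error as horizontal bars. The G2/M list lies at -0.47 in epithelium and 0.079 in mesenchyme.

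Within the epithelial classes the question was which differences remain when the mix of classes is set aside. In tip-like cells Ptf1a stood at 54.4 CPM (95% interval 47.1 to 62.3) in the control library and 124 (113 to 136) in the knockout-labelled library and Reg1 at 76.2 against 174 CPM, with Serpina1b and Scand1 as the other 2 highest. The digestive enzyme genes of the same cells were lower, with Ctrb1 at 3217 against 1884 CPM, Cpa1 at 2935 against 1786 CPM and Clps at 2478 against 1719.6 CPM, and the acinar list had a median of -0.36 (interval -0.53 to -0.23). The lowest named genes in tip-like cells were the mitotic Ube2c, Hmmr and Ccnb1 and the metallothionein Mt1, with log2 ratios of -1.39, -1.35, -1.27 and -1.31, and the G2/M list had a median of -0.67 (interval -0.76 to -0.63). Different clusters held most tip-like cells of the libraries, cluster 7 the largest part in the control library (37.8%, against 22.5%) and cluster 5 in the knockout-labelled library (51.8%, against 8.51%). Without cluster 5, chosen after seeing the data, the tip-like log2 ratios were 0.90 (0.63 to 1.17) for Ptf1a and 0.79 (0.55 to 1.03) for Reg1, and the medians -0.35 (-0.54 to -0.31) for the acinar list and -0.18 (-0.26 to -0.13) for the G2/M list. The S phase list had a median of -0.31 (interval -0.35 to -0.23) in tip-like cells, and 37 of 44 measured members were lower. Without cluster 5 it was 0.10 (0.027 to 0.15). That setting left out 51.8% of the knockout-labelled and 8.51% of the control tip-like cells, picked by their cluster. The values without cluster 5 thus describe the remaining cells and do not test the differences in tip-like cells.

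In trunk-like cells the transcription elongation factor Tcea3, Scand1, Eif3f and Serpina1a were highest, with log2 ratios of 1.15, 1.05, 0.94 and 0.89. The acinar genes Ctrb1 (70.8 against 14.4 CPM) and Clps (588 against 236 CPM) and the metallothioneins Mt2 (312 against 106 CPM) and Mt1 (506 against 183 CPM) were lowest. The acinar list had a median of -0.57 (interval -0.78 to -0.45), and 9 of 11 measured members were lower. With doublets removed at 2 times the rate this median was -0.22. G2/M genes had a median of -0.47 (interval -0.54 to -0.43) in trunk-like cells, and the cluster led by mitotic genes, number 2, held 29.1% of the control and 15.6% of the knockout-labelled trunk-like cells. Stress genes such as Atf3 and Nr4a1 were among the leading genes of trunk-like cluster 3.

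Endocrine progenitor-like cells numbered 123 in the control library and 48 in the knockout-labelled library. Neurog3 stood at 4046 CPM (95% interval 3922 to 4174) in the control library and 3137 (2973 to 3309) in the knockout-labelled library in them, a log2 ratio of -0.37 against -0.87 over the whole epithelium. The endocrine progenitor list had a median of -0.19 (interval -0.31 to -0.069) in them, and 17 of 23 measured members were lower. Chtf8, Trim27, Nefm and Actn3 had the highest log2 ratios (1.46, 1.40, 1.36 and 1.32) and Upp1, Mt2, H2-D1 and Srprb the lowest (-1.95, -1.85, -1.48 and -1.43). Chtf8, Trim27 and Actn3 had at most 29 UMIs in a library. Endocrine-like cells numbered 91 in the control library and 24 in the knockout-labelled library, and in them Iapp stood at 1472 against 27.7 CPM and Gcg at 4931 against 1949.8 CPM. The hormone and islet list as a whole had a median of -0.071 (interval -0.24 to 0.016) in these cells, which covers 0, and 13 of its 28 measured members were higher. Iapp was seen in 40 of 91 control and 5 of 24 knockout-labelled and Gcg in 24 of 91 control and 6 of 24 knockout-labelled endocrine-like cells, and for both genes the intervals of these shares overlap. No UMI of Ins1, Sst or Hhex was seen in those of the knockout-labelled library, against 168, 142 and 90.04 CPM in control cells. Ins1 was seen in 12 of 91 control cells (13.2%, interval 7.00 to 21.9) and 0 of 24, for which the limit of 3 counts of the cells is 12.5%. Sst was seen in 2 of 91 control and 0 of 24 knockout-labelled, so for neither gene was a difference in the share of cells detectable at this depth. The other insulin gene, Ins2, was seen in 8 of 91 control and 2 of 24 knockout-labelled endocrine-like cells. In mesenchyme-like cells Ins2 was seen in 5 of 2566 and 1 of 2047. Endov, Rock2, Asf1a and Gin1 were the highest, each from at most 16 UMIs in a library. Isl1 was seen in 70 of 91 control and 19 of 24 knockout-labelled endocrine-like cells. Without thinning, the mesenchyme-like cells with a UMI in the control and the knockout-labelled library, as a background, were 462 of 2566 and 466 of 2047 for Isl1, 39 of 2566 and 1 of 2047 for Gcg, 19 of 2566 and 1 of 2047 for Ghrl, 13 of 2566 and 0 of 2047 cells (limit 0.147%) for Iapp, 1 of 2566 and 0 of 2047 cells (limit 0.147%) for Ins1 and 2 of 2566 and 0 of 2047 cells (limit 0.147%) for Sst.

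Mesenchyme-like cells served as cells of the same embryos outside the epithelium. The Notch target and repressor Hes1 (chromosome 16, 30064384 to 30067796) stood at 1571 CPM (95% interval 1552 to 1591) in the control library and 772 (758 to 786) in the knockout-labelled library. The matrix genes Aspn and Col6a1, the early response gene Nr4a1, Pycard and the receptor Pdgfrb were also lowest, with log2 ratios of -1.16, -1.04, -1.03, -0.97 and -0.93. Hmga2, a chromatin protein of early development, stood at 268 against 450.0 CPM, and Scand1, Eif3f, Stmn2, Polr2m and Vapa were the other highest (1.13, 0.91, 0.90, 0.75 and 0.71). G2/M genes had a median of 0.079 (interval 0.050 to 0.11) here. One mesenchyme-like cluster, number 1, held 848 of the 2566 control cells and 341 of the 2047 cells of the knockout-labelled library, while cluster 2 held 371 and 448, and the values above are not separated by cluster.

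In mesothelium-like cells, which line the organ, Rprm (10.8 against 72.2 CPM) and Apela (10.4 against 51.5 CPM) had the highest ratios, followed by Eif3f and Yipf4 (1.08 and 0.97). The mitotic genes Ccnb1, Plk1 and Aurka and the importin Kpna2 had the lowest (-1.33, -1.19, -1.15 and -1.13), and the G2/M list had a median of -0.74 (interval -0.80 to -0.68). As shares of all UMIs, G2/M genes took 0.639% and 0.452% in the epithelium, 0.743% and 0.455% in the mesothelium and 0.494% and 0.527% in the mesenchyme of the control and the knockout-labelled library.

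The authors' deposited table lists 4691 entries for 7 clusters and compares each cluster with the other cells, not knockout with control. In the authors' deposited table, cluster 1 is led by Gcg, Pyy and Slc38a5, cluster 4 by Neurog3 and Cck, cluster 2 by Ube2c and Cenpf, and cluster 3 by Ctrb1 and Spink1. The 50 leading genes of cluster 1 in the authors' deposited table had a median log2 ratio of -0.89 in the epithelium computed here, those of cluster 4 one of -0.56, those of cluster 2 one of -0.56 and those of cluster 3 one of 0.18. Clusters 5 (S phase genes), 6 (with Cpa1 among its leading genes) and 7 (Spp1, Cyr61) of the authors' deposited table gave -0.073, -0.14 and -0.032. These lists are cluster markers from the same series, so their medians follow in part from the class shares above and are no separate support.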

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

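No test was run in this part, and the setting without epithelial cluster 5 was chosen only after the result was seen. The differences between classes were not tested, with 1 library per group, and are given because the list medians had opposite signs in epithelium and mesenchyme. The G2/M genes were lower in the epithelium of the knockout-labelled library (median log2 ratio -0.47, and -0.28 without cluster 5), with a median close to 0 in its mesenchyme (0.079). They were also lower in its mesothelium (-0.74, 51 of 52 lower), so the difference is not particular to the epithelium. For S phase genes the medians were -0.070 in epithelium and 0.050 in mesenchyme, and without cluster 5 the epithelial median was 0.094, so no direction is read from these. In single classes the S phase median was -0.31 in tip-like cells (37 of 44 lower), -0.30 in endocrine progenitor-like cells (24 of 33), -0.024 (interval -0.074 to 0.041) in trunk-like cells (24 of 44), -0.084 (interval -0.46 to 0.38) in endocrine-like cells (6 of 10) and -0.19 in mesothelium (30 of 44). In tip-like cells without cluster 5 it was 0.10 (0.027 to 0.15). Leaving out cluster 5 removes mainly knockout-labelled cells, so the values without it describe the remaining cells and test no difference.

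A cluster that met no name, with Igf1, Nrxn3, Nrk and Stmn2 among its leading genes, stood out in data outside the comparisons. It held 1.40% of the non-erythroid cells of the knockout-labelled library (41 of 2929, interval 1.01 to 1.89) and 0.294% of those of the control library (11 of 3742, 0.147 to 0.525). The cluster scored best for mesenchyme, with 7 markers detected but 0 among its 10 leading genes. The mesenchyme values leave it out.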

How the results depend on the processing

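Leaving out marker and list genes from the clustering, leaving out epithelial cluster 5 and combining classes at equal shares of UMIs were chosen after seeing the data. Of 1190 values recomputed for 54 results, 1007 stayed within the counting interval, 179 moved outside it, and 4 changed the sign of a value whose interval excluded 0. Of all values, 23 lay on the other side of 0 (log2) or 1 (ratios of shares) from the value reported, and for 19 of them the reported interval covered that point, namely for the acinar, p53 target, Hox, glycolysis and other endoderm lists and the trunk-like and mesenchyme-like shares. The ratios of the endocrine-like and endocrine progenitor-like shares and of the Neurog3-positive share stayed within their intervals under each alternative run for them, but without cluster 5 those of the endocrine progenitor-like and Neurog3-positive shares, 0.775 (0.569 to 1.06) and 0.838 (0.667 to 1.05), have intervals that include 1. That setting raises these ratios through the denominators by construction. No paired analysis was possible because each group is 1 library, numbered in accession order, and no test was run. The shares and list medians (log2) that moved were, by setting, as follows. With stricter cell filter: share of mesenchyme-like 0.976 and mitochondrially encoded 0.27. With no doublets removed: share of acinar or tip-like 1.38. With Leiden resolution 2.0: share of mesenchyme-like 0.934. With epithelial cells by a gate on UMIs: G2/M -0.46. With median-of-ratios size factors: G2/M -0.44 and mitochondrially encoded 0.28. With TMM factors: G2/M -0.45 and mitochondrially encoded 0.28. With mean over cells of each cell's CPM: duct and trunk -0.085, endocrine progenitor -0.69, G2/M -0.42 and mitochondrially encoded 0.20. With CPM without haemoglobin, mitochondrial and ribosomal genes: S phase -0.028, G2/M -0.46, imprinted 0.10, glycolysis and hypoxia 0.086 and mitochondrially encoded 0.29. With cells thinned to 3000 UMIs: acinar 0.16, G2/M -0.42, mitochondrially encoded 0.19 and Dpy30 0.14. With pseudocount 1 CPM: endocrine progenitor -0.69 and endocrine hormone and islet -1.43. With pseudocount 20 CPM: endocrine progenitor -0.38, endocrine hormone and islet -0.62 and G2/M -0.37. With list members with at least 1 UMI: dissociation stress -0.21. With list members with at least 100 UMIs: acinar 0.16. With mean of the class ratios: duct and trunk -0.090, endocrine progenitor -0.070, endocrine hormone and islet -0.31, S phase -0.15, Hox and other Polycomb target 0.23 and dissociation stress -0.13. With epithelial minus mesenchymal ratio: acinar 0.17, duct and trunk -0.053, endocrine hormone and islet -0.998, S phase -0.14, G2/M -0.60, imprinted 0.18, dissociation stress -0.20, glycolysis and hypoxia -0.055, mitochondrially encoded -0.066, Dpy30 0.027 and Scand1 -0.048. Without epithelial cluster 5: acinar -0.32, duct and trunk -0.032, endocrine progenitor -0.42, endocrine hormone and islet -0.97, S phase 0.094, G2/M -0.28, dissociation stress -0.21, share of epithelium-like 0.663, share of acinar or tip-like 1.06 and share of trunk or duct-like 1.17. With equal class shares of UMIs: acinar -0.21, duct and trunk -0.087, endocrine progenitor -0.072, endocrine hormone and islet -0.13, S phase -0.16, Hox and other Polycomb target 0.21, dissociation stress -0.21 and Slc38a5 0.0049. Among values whose interval excluded 0, the sign changed for mitochondrially encoded genes and Scand1 with the mesenchymal ratio subtracted, which by its construction removes what both classes share, for S phase without cluster 5, and for Slc38a5 at equal class shares of UMIs. For genes low in mesenchyme that subtraction is not read, since UMIs there can be free epithelial RNA. Mt1, Chgb and most hormone and acinar genes are such genes. The mean of the class ratios, weighted by share of cells, draws genes of 1 class toward 0 by construction. Pseudocounts of 1 and 20 change low genes by construction. For the other values the cause was not tested. The endocrine-like and immune-like classes had 24 and 23 cells in the knockout-labelled library, which limits their values.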

Other observations

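The tests of depth, of the clustering behind the endocrine shares, of embryo age, of the genes outside chromosome 17 and of free RNA were chosen only after the result was seen, as were the settings without marker and list genes and without epithelial cluster 5.

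Several genes not described above differed in endocrine progenitor-like cells, and they were chosen after their values were seen. Sox9, a transcription factor of the trunk, stood at 51.8 CPM (95% interval 38.6 to 68.1) in the control library and 120.0 (89.6 to 157) in the knockout-labelled library. Hhex stood at 8.12 against 39.2 CPM and the chromatin protein Hmga2 at 61.9 against 145 CPM, all higher in the knockout-labelled library, while 8 of 13 measured members were lower in the duct and trunk list, with a median log2 ratio of -0.19 (interval -0.33 to -0.0094). Hhex lay under the 50 CPM minimum of the naming rule in both libraries, so its ratio rests on few UMIs. The Notch target Hes1 was lower, at 192 against 73.8 CPM, while the intervals of the Notch ligand Dll1 overlapped (82.2 against 48.4 CPM). Neurod1, which acts after Neurog3, stood at 197 against 279 CPM, and Pax4 at 245 against 217 CPM with overlapping intervals. In trunk-like cells Neurog3 stood at 80.3 against 92.3 CPM, with overlapping intervals. The metallothionein Mt2 was lower in tip-like and trunk-like cells of the knockout-labelled library, at 678 against 380.4 CPM and 312 against 106 CPM, and its log2 ratio was -0.36 in mesenchyme.

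The shares of endocrine progenitor-like and endocrine-like cells were lower. Without epithelial cluster 5 the ratios were 0.775 (0.569 to 1.06) and 0.524 (0.340 to 0.807) and that of Neurog3-positive cells 0.838 (0.667 to 1.05). Of these only the endocrine-like interval excludes 1. Leaving out cluster 5 raises these ratios through the denominators by construction, so this setting does not decide whether the endocrine shares differ. At 3000 UMIs per cell the ratio of Neurog3-positive shares was 0.676 and that of Chga-positive shares 0.418, with upper bounds of 0.853 and 0.628, which argues against depth. The knockout-labelled epithelium was the deeper on median (12127 against 14325.5 UMIs). Depth would thus tend to raise its shares, and thinning had little room to show depth as the cause. Clustering without marker and list genes gave an endocrine-like ratio of 0.405 (upper bound 0.637), which argues against clustering on those genes. For a younger embryo behind the knockout label, 4 measured genes of early stages (Hmga2, Igf2bp1, Igf2bp2 and Igf2bp3) had a median log2 ratio of 0.086 in mesenchyme, with members on both sides of 0, and -0.050 in mesothelium. With 1 embryo per group, embryo age cannot be told apart from genotype, which stays an untested explanation, as does sex.

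A set of 8 genes was at least 1.5-fold higher in the knockout-labelled library in each of epithelium, mesenchyme and mesothelium, namely Abhd17a, C1qbp, Dcun1d5, Eif3f, Polr2m, Rala, Scand1 and Vapa. Of these genes 0% lay on the X chromosome (upper bound 36.9%), which argues against X dosage as the cause of most of them. On chromosome 17, which carries Dpy30, lay 12.5% (Vapa, upper bound 52.7%), and a linked segment cannot reach the 87.5% on other chromosomes. Yipf4, outside this set, lies nearer to Dpy30 (74489493 to 74500277) than Vapa does (65578327 to 65613555). Its log2 ratios were 0.49 in epithelium, 0.75 in mesenchyme and 0.97 in mesothelium. For Vapa and Yipf4 a linked segment cannot be told apart from genotype. The trend in GC content and length of each gene's longest transcript reached at most 0.12 in log2. With it removed, the epithelial median was 0.69 against 0.66 before, which argues against that trend alone. The composition of the counted 3' ends was not tested. Genotype and other differences between these embryos or preparations stay open and untested.

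The lower acinar genes in trunk-like cells were weighed against free RNA, doublets and class borders. These genes took a share of UMIs in trunk-like cells 10.1 times that in mesenchyme of the knockout-labelled library. In the control library it was 13.6 times. This argues against free RNA as the main source of their pooled UMIs. The pooled share gives most weight to genes with many UMIs, such as Clps, and does not test the list median. The acinar list was also lower in mesenchyme (median log2 ratio -0.18, 10 of 11 measured members lower) and mesothelium (-0.49, 6 of 7). Less free RNA of acinar genes in the knockout-labelled library may therefore contribute to the lower trunk-like median, by an amount this test cannot decide. For the acinar gene Cpa1, the thinned shares of mesenchyme-like cells with a UMI were close, at 7.53% and 7.15%. Clustering without marker and list genes gave a trunk-like median log2 ratio of -0.61, which argues against class borders drawn on those genes. With doublets removed at 2 times the rate and the classes drawn again, the trunk-like median was -0.22 (interval -0.50 to -0.084), and -0.57 before. The interval still excluded 0, but removal by score can leave doublets behind. Doublets of tip-like and trunk-like cells may therefore account for part or all of the difference, which this test cannot decide. Genotype stays an untested explanation.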
